A study of Homo sapiens with 3 samples.

How the data were processed

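RNA was measured in 3 samples on 1 array each: unirradiated LNCaP C4-2 cells with the vector pLXSN, and cells with GSE56 at 6 h and at 24 h after 10 Sv. Per the labels, scans of HG-U95Av2 arrays were processed by the authors with Microarray Suite 5 and then with GeneSpring, whose settings are not given in the sources used here. The deposited values are intensities, taken from the values themselves to be on a linear scale with each array divided by its own median, a step no label states: every array has a median of 1 and a lowest value of 0.01. Multiplying them by 93.6 (control), 103.5 (6 h) and 100.9 (24 h) turned 99.7%, 99.8% and 99.7% of the values above the lowest one into multiples of 0.1 within 0.02 of such a step. On that scale the means trimmed by 2% at each end were 300.1 on all 3 arrays, so the arrays agree in their trimmed means before the division by the median and not after it.

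Samples were grouped by the labels' source and description, which give the control as vector cells without the GSE56 insert; sample titles carry the series' name and a time and were not used. The choices below were made before the data were examined. Values were used as deposited if the trimmed means of the arrays agreed within 5%, and otherwise after quantile normalization of the log2 values. The deposited trimmed means were 3.21, 2.90 and 2.97, a spread of 10.6%, so quantile normalization was used. The floor was the pooled 50th percentile of the probe sets other than controls, and lower values were raised to it before log2 differences were taken. A fold against a value below the floor is a lower bound.

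Probe sets were named through the platform annotation supplied with the values. Of the probe sets, 11506 were listed there, 10961 with 1 gene symbol and 545 with several, and 1119 were unnamed here. The gene identifiers of 10949 matched the current gene table and 0 symbols changed. Where a gene had several probe sets, as for 1928 of the 8226 genes, the one with the highest mean log2 level over the 3 arrays was used. The 67 control probe sets entered the quantile normalization and no gene. All 3 columns of values were used, and no genome build is named in the files, so no coordinates are given.

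Genes at least 2-fold different were counted. Genes were named by rule: the 10 largest differences in each direction measured on both arrays, the 4 largest in each direction with 1 value below the floor, and up to 4 members with a 2-fold difference from each list, or the 2 most abundant members where a list had none, of which a few are printed. The 5 p53 targets CDKN1A, MDM2, GADD45A, BAX and FAS were given on every array. VIM, COL6A2 and genes that the closing section names beyond these were chosen after their values were seen. For each of 21 gene lists the median log2 difference was set against the medians of 10000 random lists of as many genes, drawn in 20 bins of mean level. A list stands apart when its median lies outside the central 95% of these medians, which describes these arrays and is no significance test. Lists whose members lie mostly below the floor have a median of 0 by construction.

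Array quality was read from control probe sets. The ratio of the 3' to the 5' GAPDH probe set was 1.42, 1.41 and 1.43 on the control, 6 h and 24 h arrays, and that of beta-actin 1.66, 1.57 and 1.66. The 9 hybridization controls had a median ratio to the control array of 1.08 at 6 h and 0.662 at 24 h, with a range of 0.482 to 0.824 at 24 h. The 15 bacterial poly-A control probe sets were at most 0.522.

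The counting and the list percentiles were tested on simulated arrays built from the real levels and the measured probe set noise, over 8226 genes with 200 changed genes and 20 repeats. For the 6 h, 24 h and 24 h against 6 h comparisons, 50.7%, 49.4% and 50.0% of genes changed 2-fold and 99.8%, 99.9% and 100.0% of genes changed 4-fold were called. The changed genes were drawn only from genes with a mean level at least 4 times the floor, so these rates leave out lower genes. A simulated 2-fold change lies on the threshold itself, so its rate was set by construction. A list of 43 genes shifted by 0.3 stood apart in 20 of 20 repeats and the unshifted list in 0 of 20, in each comparison. This was the list of G1/S and DNA replication, with nearly all members above the floor, so it does not speak for lists mostly below it. The simulated noise leaves out variation between cultures, harvests and arrays, so these rates hold for the probe set noise only.

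Alternatives were values as deposited, scaling to array medians, loess scaling of each pair with a span of 0.4, floors at the 30th and 70th percentile and none, the median over a gene's probe sets, probe sets without a suffix letter, fold thresholds of 1.5 and 3, and random lists not matched on level. Scaling to trimmed means, list medians over members above the floor, and counts without probe sets marked r, f or i in their names were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.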

Results

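RNA from LNCaP C4-2 cells, an androgen-independent human prostate adenocarcinoma line, was measured on 3 Affymetrix HG-U95Av2 oligonucleotide arrays. The control array carried RNA of cells transfected with the empty retroviral vector pLXSN and left unirradiated. The other 2 arrays carried RNA of cells that stably expressed GSE56, a peptide that suppresses p53 function, collected 6 h and 24 h after 10 Sv of gamma rays from a caesium source. The control cells were collected together with the 24 h cells. Each group had 1 array, so no difference has a replicate check, no p-value is given, and the number of arrays limits the precision. Both comparisons with the control combine the GSE56 insert with irradiation, since neither unirradiated GSE56 cells nor irradiated vector cells were analysed here.

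Each array reported 12558 probe sets besides 67 controls, and 8226 genes were compared after 1 probe set was chosen for each gene. Levels are given as multiples of the array median after quantile normalization. Between 6278 and 6281 probe sets of an array lay at or above the floor, which was the pooled median level. Across probe sets above the floor on both arrays, the log2 levels of each pair of arrays correlated with a Pearson coefficient of 0.970 for 6 h and control, 0.956 for 24 h and control and 0.958 for 24 h and 6 h; this is across probe sets, which are not independent replicates. Different probe sets of the same gene gave log2 differences with a standard deviation (SD) of 0.35, 0.34 and 0.31 in the 3 comparisons, over 644, 625 and 628 genes. This SD serves below as a yardstick for a single gene's difference. It compares probe sets on the same arrays and leaves out variation between cultures, harvests and arrays, so it is not the error of a difference between groups.

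The labels describe suppressed p53 function, so 5 known p53 targets were examined first. CDKN1A, the cyclin-dependent kinase inhibitor p21, had a level of 2.94 on the control array, 4.10 at 6 h and 9.73 at 24 h. GADD45A, a DNA damage-inducible gene, had levels of 2.56, 4.48 and 4.15 on the same arrays. BAX, a promoter of apoptosis, had levels of 5.96, 5.75 and 9.84; its 4 other probe sets had a median log2 difference from the control of 0.32 at 6 h and 0.74 at 24 h. MDM2 and FAS were below the floor on all 3 arrays, and the transcript of the p53 gene itself was not analysed here.

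The first comparison asked how GSE56 cells 6 h after irradiation differed from unirradiated vector cells. Genes of mitosis were lower on the 6 h array: CDC20, an activator of the anaphase-promoting complex, by 3.97-fold, CCNB1, the mitotic cyclin B1, by 3.34-fold, TROAP by 3.51-fold and HMMR by 2.62-fold. Of 41 measured genes of mitosis and G2/M, 36 were below the control, 11 of them at least 2-fold, none was at least 2-fold higher, and the median log2 difference was -0.68. Genes of G1/S and DNA replication lay the other way: 32 of 43 were above the control with a median of 0.31, although none reached 2-fold, and POLD1, a catalytic subunit of DNA polymerase delta, was at least 2.34-fold lower. The medians of these 2 lists lay at percentiles 0 and 100 among 10000 random lists matched on level. The mitosis median was -0.44 with the floor at the 70th percentile, and the replication median was 0.20 with arrays as deposited.

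Of 29 measured p53 targets, 2 were at least 2-fold higher at 6 h. These were TRIAP1, an inhibitor of p53-dependent apoptosis, at 2.72-fold, and DDB2, a damage recognition protein of nucleotide excision repair, at 2.14-fold. The median of the list was 0.056, at percentile 96.5, which did not stand apart from random lists. It did stand apart with 5 of the 9 other settings, among them arrays as deposited (median 0.0034, percentile 99.95) and the median over the probe sets of a gene (median 0.16, percentile 100).

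In all, 28 genes were at least 2-fold higher and 67 at least 2-fold lower at 6 h. With arrays as deposited the split was 24 higher and 92 lower, and with trimmed-mean scaling 36 and 57. The higher genes measured on both arrays were led by PTGDS at 3.03-fold, TRIAP1, MPPE1 at 2.40-fold, KCTD17 at 2.39-fold, ITFG2 at 2.26-fold, INHBC at 2.26-fold, OBSL1 at 2.25-fold, MNAT1 at 2.20-fold, VARS1, a valyl-tRNA synthetase, at 2.14-fold, and DDB2. For PTGDS and MNAT1 the direction depended on the probe set, since suffix-free probe sets gave log2 differences of -1.31 and -0.37. The lower genes were led by ARR3 at 7.12-fold, RTEL1 at 4.45-fold, KIF1C at 4.42-fold, MSI1 at 4.26-fold, CDC20, TROAP, MUC5AC at 3.38-fold, CCNB1, PRICKLE3 at 3.15-fold and FKBP8 at 2.91-fold. Against values below the floor, BFSP2 was at least 3.16-fold, TLX1 at least 3.14-fold, CDH15 at least 2.81-fold and SHBG at least 2.78-fold higher. WNT11 was at least 4.25-fold, NAB2 at least 3.37-fold, FARP2 at least 3.33-fold and GPR12 at least 3.07-fold lower.

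Among the other lists, 27 measured genes of sterol and fatty acid synthesis had a median of 0.13 (percentile 98.3) and 47 genes of the respiratory chain and ATP synthase one of 0.085 (percentile 99.0), with no member 2-fold different in either. The first median was 0 and no longer stood apart with arrays as deposited, scaled to their medians, or with the floor at the 70th percentile. With arrays as deposited the second was -0.10, still above random lists at percentile 98.2. The respiratory chain no longer stood apart with the median over probe sets (0.054) or with suffix-free probe sets (0.069). No member was 2-fold different at 6 h among 20 histone genes, 40 DNA repair genes, 34 NF-kB targets, 28 immediate early genes, 44 interferon-stimulated genes or 41 apoptosis regulators. The same held for 29 androgen-responsive genes, 35 genes of unfolded protein and amino acid stress, 24 heat shock genes, 30 genes of glycolysis and hypoxia, 46 ribosomal protein genes and 31 proteasome genes. None of these 12 lists stood apart at 6 h with the main settings. Ribosomal proteins stood apart below random lists as deposited and with median or trimmed-mean scaling (-0.32, -0.32 and -0.17). Histone genes did so with loess scaling (-0.027), no floor (-0.27) and the median over probe sets (-0.0054). Interferon-stimulated genes stood apart above with the floor at the 30th percentile (0.16) and with none (0.25). The histone variant gene H2AX, which marks DNA breaks when phosphorylated, had a log2 difference of -0.81 and NFKB1, an NF-kB subunit, one of 0.74, against -0.37 on other NFKB1 probe sets. H2AZ1 and NFKBIA, the other members of these lists named by the rule, had smaller log2 differences of 0.064 and 0.12. Markers of neuroendocrine cells (21 genes), fibroblasts (24), leukocytes (21) and basal epithelium (14) had medians of 0, with no member 2-fold different on the chosen probe set. Another probe set of the fibroblast marker COL6A1 gave a log2 difference of 1.59, against 0.46 on the chosen one.

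**Figure D1:**
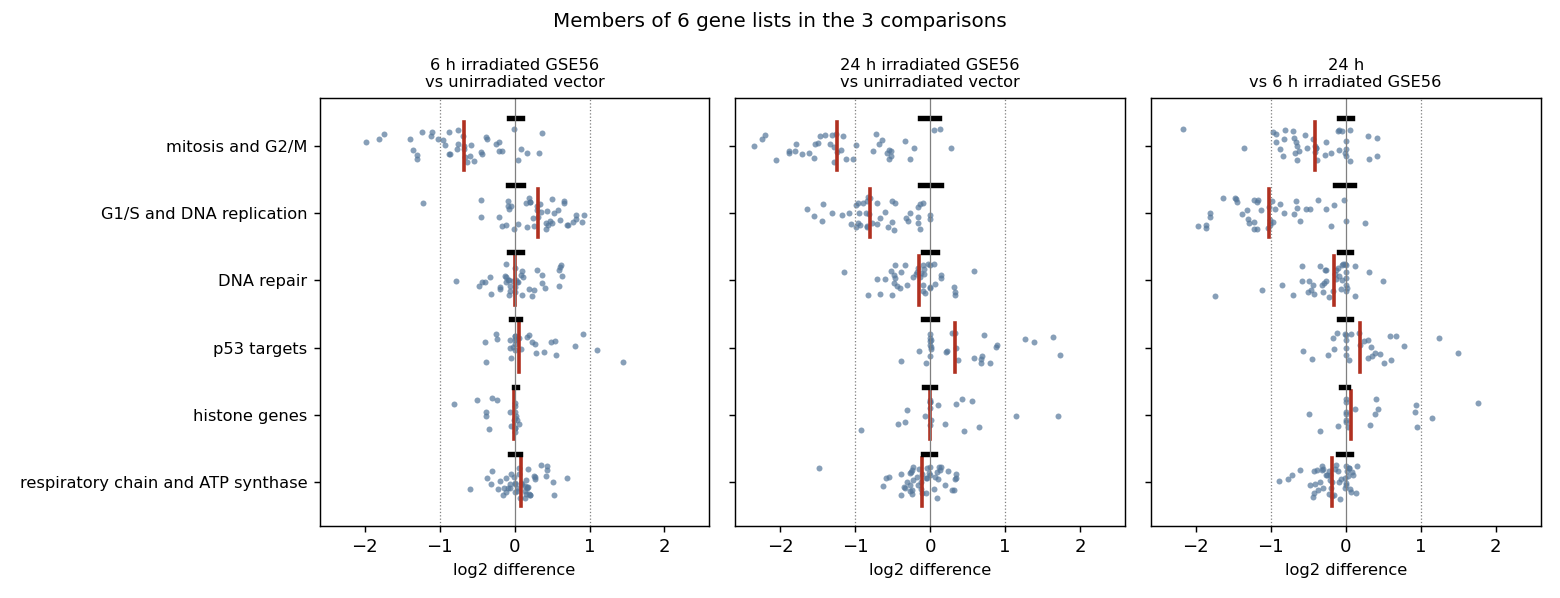
Log2 differences of the members of 6 gene lists in the 3 comparisons, with 1 point for each gene, a red line at the list median, a black bar for the central 95% of the medians of random lists, and dotted lines at a 2-fold difference. Mitosis genes had medians of -0.68 at 6 h and -1.24 at 24 h, and replication genes had medians of 0.31 at 6 h and -0.81 at 24 h.

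At 24 h after irradiation the mitosis genes lay further below the control. PTTG1, the securin that holds back sister chromatid separation, was lower by 5.09-fold, CDC20 by 4.74-fold, TPX2, a spindle assembly factor, by 4.18-fold, the kinase gene AURKA by 3.69-fold and CCNB1 by 3.45-fold. Of the 41 measured genes of mitosis and G2/M, 25 were at least 2-fold lower and none at least 2-fold higher, with a median of -1.24. Replication genes were now below the control as well: 8 of 43 were at least 2-fold lower, no member was above the control, and the median was -0.81. PRIM1, a primase subunit, was lower by 3.12-fold, CDC45 by 2.92-fold, RFC2 by 2.72-fold and the thymidine kinase gene TK1 by 2.70-fold, with a smaller log2 difference of -0.91 on another TK1 probe set. Both lists lay at percentile 0 of the random lists. With the floor at the 70th percentile the replication median was -0.32, with 3 members at least 2-fold lower, and with arrays as deposited 14 members were.

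The p53 targets were above the control at 24 h. Of 29 measured members, 4 were at least 2-fold higher, none was 2-fold lower, 21 lay above the control, and the median of 0.34 lay at percentile 100. CDKN1A was higher by 3.31-fold, TRIAP1 by 3.11-fold, DDB2 by 2.62-fold and CCNG1, cyclin G1, by 2.41-fold. With a floor at the 70th percentile the median was 0.0099, with 2 members at least 2-fold higher. With the median over the probe sets of a gene the list median was 0.19. With suffix-free probe sets it was 0.22 over 24 members, which leaves out CDKN1A and CCNG1. Of 40 DNA repair genes, 29 lay below the control, and RAD54L, of homologous recombination, was the single member at least 2-fold lower, at 2.21-fold (-0.57 on another probe set). The list's median of -0.15 lay at percentile 0.31. It was 0 with the floor at the 70th percentile.

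In all, 74 genes were at least 2-fold higher and 105 at least 2-fold lower at 24 h. With arrays as deposited the split was 59 higher and 141 lower, and with arrays scaled to their medians 59 and 143. The higher genes measured on both arrays were led by CCL20, a chemokine, at 4.07-fold, LCN2, lipocalin 2, at 3.95-fold, EVX1 at 3.84-fold, CDKN1A, H2BC21, a histone H2B gene, at 3.27-fold, TRIAP1, KCTD17 at 3.10-fold, CFAP410 at 2.91-fold, EDA at 2.65-fold (0.41 on another probe set), and DDB2. The lower genes were led by PTTG1, CDC20, NDC80, a kinetochore gene, at 4.62-fold, TPX2, GCG at 3.82-fold, AURKA, KIF11 at 3.67-fold, KIF2C at 3.48-fold, CCNB1 and KIF14 at 3.27-fold. Against values below the floor, NEU1 was at least 3.52-fold, CHPF at least 3.20-fold, PTPRS at least 3.02-fold and CSPG4 at least 2.87-fold higher. RMND5B was at least 4.75-fold, TROAP at least 4.59-fold, IRF2BP1 at least 3.58-fold and DRD2 at least 3.28-fold lower.

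Members of other lists also differed 2-fold at 24 h. Among 20 histone genes H2BC21 and H2BC5 were higher, the second by at least 2.22-fold, and among 34 NF-kB targets CCL20 and NFKB2 were higher, the second by 2.32-fold, with a log2 difference of 0.40 on another probe set. Of 35 genes of unfolded protein and amino acid stress, PPP1R15A (at least 2.52-fold), CBS (2.19-fold) and HSPA5 (2.16-fold), which encodes the chaperone BiP, were higher and DDIT4 was 2.11-fold lower. HLA-E was at least 2.06-fold higher among the interferon-stimulated genes, EBP 2.21-fold lower among the sterol genes, PSMA7 at least 2.48-fold lower among the proteasome genes and ATP5F1B 2.80-fold lower in the respiratory chain. The respiratory chain median of -0.11 lay at percentile 1.30, and it was -0.24 both with arrays as deposited and scaled to their medians. None of the other lists in this paragraph stood apart at 24 h with the main settings. S100A4 was 2.06-fold higher among the fibroblast markers, and no other marker of another cell type or state differed 2-fold; these 4 lists had medians of 0. The immediate early, androgen-responsive, apoptosis, heat shock and ribosomal lists had no member 2-fold different and did not stand apart. Under other scalings the ribosomal list stood apart above random lists in 4 of 4, with medians from -0.012 to 0.098, and the immediate early list stood apart below them with arrays as deposited (-0.066) and scaled to their medians (-0.068). Without a floor the NF-kB median was 0.28 and the interferon median 0.24, and both stood apart, the second also with the floor at the 30th percentile (0.096). DDIT4 was the only 2-fold member of the glycolysis and hypoxia list, whose median of 0.0016 did not stand apart.

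According to the labels, the 24 h and 6 h arrays, both of irradiated GSE56 cells, differ by the time after irradiation alone, which goes together with the time of harvest. Replication genes were lower at 24 h: CDC45 by 3.94-fold, CDC6, a loader of the replicative helicase, by 3.62-fold, RFC2 by 3.62-fold and MCM3, a helicase subunit, by 3.52-fold. Of 43 measured members 25 were at least 2-fold lower, none was 2-fold higher, and the median was -1.03. Of the 41 mitosis genes, PTTG1 was lower by 4.52-fold and CDK1 by 2.57-fold, and the list's median was -0.41. CDC6 and CDK1 had other measured probe sets with smaller median log2 differences of -0.87 and -0.71. Both lists lay at percentile 0. With the floor at the 70th percentile the mitosis median was -0.18 and the replication median -0.67, with 13 replication genes at least 2-fold lower.

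The p53 targets CCNG1 and CDKN1A were 2.82-fold and 2.37-fold higher at 24 h than at 6 h, and the list's median of 0.19 lay at percentile 99.91. It was 0 with the floor at the 70th percentile and 0.062 with suffix-free probe sets, which leave out both genes. Among the histone genes H2BC21 was 3.39-fold and H2BC5 at least 2.22-fold higher, with a list median of 0.075 (percentile 99.3) that was 0 with the floor at the 70th percentile and with suffix-free probe sets. DNA repair genes had a median of -0.15 (percentile 0.18), with RAD54L 3.36-fold (-0.79 on another probe set) and FANCG 2.16-fold lower; the median was 0 with the floor at the 70th percentile.

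In all, 76 genes were at least 2-fold higher and 88 at least 2-fold lower at 24 h than at 6 h. The balance turned to 80 higher and 73 lower with arrays as deposited, and to 80 and 74 with arrays scaled to their medians. The higher genes were led by ARR3 at 7.89-fold, CCL20 at 5.07-fold, LCN2 at 4.71-fold, EVX1 at 4.14-fold, MSI1 at 4.01-fold, FKBP8 at 3.97-fold, RTEL1 at 3.92-fold, H2BC21, MUC5AC at 3.34-fold and S100P, a calcium-binding protein, at 3.27-fold. ARR3, EVX1 and MSI1 rested on probe sets marked r in their names. ARR3, MSI1, FKBP8, RTEL1 and MUC5AC were also among the 10 genes furthest below the control at 6 h of those above the floor on both arrays. The lower genes were led by PTTG1, GCG at 4.07-fold, CDC45, CDC6, RFC2, MCM3, CCNE2, cyclin E2, at 3.50-fold, RAD54L, PRIM1 at 3.11-fold and TIPRL at 2.91-fold. Against values below the floor, FARP2 was at least 5.00-fold, CHPF at least 3.20-fold, EFNA2 at least 2.86-fold and MEG3 at least 2.69-fold higher. TLX1 was at least 3.14-fold, PSMA7 at least 2.94-fold, RAD51AP1 at least 2.75-fold and IRF2BP1 at least 2.72-fold lower.

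Lists of large complexes also stood apart between the 2 times. Respiratory chain genes had a median of -0.19 (percentile 0.025), proteasome genes one of -0.20 (percentile 0.47) and ribosomal protein genes one of 0.076 (percentile 98.7), with 11 of 46 members lower at 24 h. The ribosomal median was 0.29 as deposited, 0.29 with median scaling and 0.25 with trimmed means, and the proteasome list no longer stood apart with the median over probe sets. With arrays as deposited the respiratory chain median was -0.096. Single members of other lists differed 2-fold: IRF9 was 2.27-fold, EBP 2.15-fold, FDPS 2.02-fold and DDIT4 2.02-fold lower, and HSPA5 2.21-fold, PFKFB4 2.14-fold, BNIP3L 2.04-fold and CBS 2.02-fold higher. Of 24 fibroblast markers, 10 were above and 0 below the 6 h level on the chosen probe sets, the largest being VIM at 0.57 and COL6A2 at 0.55. Another COL6A1 probe set gave a log2 difference of -0.43, against 0.30 on the chosen one. The fibroblast list stood apart without a floor (median 0.37) and with the floor at the 30th percentile (0.055). With the main settings neither this list nor the interferon, sterol, glycolysis, unfolded protein and apoptosis lists stood apart, nor did the NF-kB, immediate early, androgen-responsive, heat shock and other cell type or state lists. The androgen-responsive list stood apart above with the median over probe sets (0.042). Over the 21 lists and 3 comparisons, 17 of 63 medians stood apart, 7 above and 10 below. The central 95% of the random medians was 0 to 0 for 19 of the 63, among them the NF-kB, interferon and other cell type or state lists in each comparison, so the floor kept their medians at 0. The 3 comparisons share arrays, so the 63 medians are not independent.

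**Figure D2:**
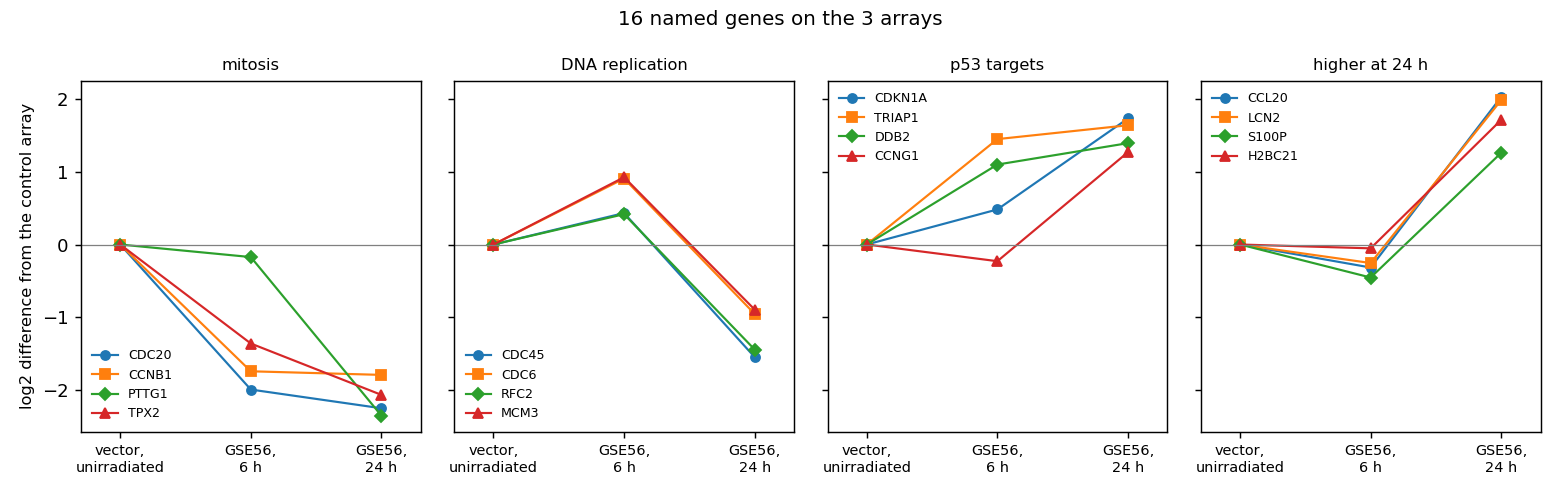
Log2 differences of 16 named genes from the control array (0) on the 6 h and 24 h arrays of irradiated GSE56 cells, with 1 point for each array. CDC20 lay at -1.99 and -2.25, CDC45 at 0.43 and -1.55, CDKN1A at 0.48 and 1.73, and LCN2 reached 1.98 at 24 h.

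The differences at 6 h and 24 h share the control array. Across the 8226 genes, which are not independent replicates, they correlated with a Pearson coefficient of 0.460 and a Spearman coefficient of 0.394, against means of 0.501 and 0.432 in 200 simulations with no change, whose noise was taken from the 24 h against 6 h difference and so is an upper estimate; the covariance was 0.0470 against a simulated 0.0607. Genes such as TRIAP1, DDB2 and KCTD17 were among 11 genes at least 2-fold higher at both times (simulated mean 8.72, range 2 to 17, independent lists 0.252). CDC20, CCNB1, AURKA and TROAP were among 27 at least 2-fold lower at both times (simulated mean 17.1, range 8 to 27, independent lists 0.855). No gene was 2-fold different in opposite directions, and none was in any simulation, so with a shared control this count says nothing about the 2 times. Both overlap counts lay within the simulated ranges, the second at its upper end. The Pearson and Spearman coefficients lay below theirs, which were 0.469 to 0.531 and 0.405 to 0.471. A single control array cannot be split, so part or all of both overlaps may come from it.

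Few calls could be checked on another probe set. Of the called genes, 6, 20 and 18 in the 3 comparisons had another measured probe set, and 4, 14 and 14 of these had the same direction. The same direction with at least a 1.5-fold difference was found for 2, 7 and 12. Probe sets marked r, f or i in their names were used for 4.23% of all genes. They held 14.3% of the higher and 11.9% of the lower genes at 6 h, and 10.8% and 0.95% at 24 h. At 24 h against 6 h they held 13.2% and 2.27%. On simulated arrays with the probe set noise, means of 12.9, 16 and 4.55 unchanged genes were called in the 3 comparisons beside genes changed 2-fold, and 13.6, 14.8 and 6.05 beside genes changed 4-fold. This noise was the same for every gene and was measured above the floor. It leaves out variation between cultures, harvests and arrays, so these means are no estimate of the false calls in the real data.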

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

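All tests of explanations in this part were chosen after the results were seen. Lists that stood apart in opposite directions at 6 h and 24 h are given first, and the difference between the times was not tested with replicates. The median of the G1/S and DNA replication genes was 0.31 at 6 h and -0.81 at 24 h. The median of the respiratory chain and ATP synthase genes was 0.085 at 6 h and -0.11 at 24 h, and with arrays as deposited or scaled to their medians the 6 h value was -0.10.

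The replication genes included MCM3 and CDC6, which lay 0.92 and 0.90 above the control at 6 h and -0.89 and -0.95 from it at 24 h. Over 4 other scalings the list's median nearest 0 was 0.20 at 6 h and -0.77 at 24 h, outside the random lists each time. Values as deposited, median scaling and trimmed-mean scaling differ from each other only by a constant for each array. Such a constant moves the random lists as well, so the rank among them cannot test it. Loess scaling also left the list outside the random lists, but these are matched on level and move with it, so this rank is no test either. The list median itself stayed at least as far from 0 as 0.20 at 6 h and -0.77 at 24 h under loess scaling. That scaling takes out differences that change with level, so these medians argue against such a difference as the whole cause. The GSE56 insert alone, if its effect was the same at both times, would leave no difference between the GSE56 arrays, where the median was -1.03. The time of harvest stays open for the 6 h part, whose value of 0.31 is taken against a control collected with the 24 h cells. It stays open for the -1.03 between the GSE56 arrays too. An insert effect joined with a harvest difference is therefore not argued against. The time after irradiation itself may account for the order, as a biological hypothesis that was not tested.

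The p53 targets were higher at 24 h in cells described as having suppressed p53 function, with 4 of 29 members, CDKN1A, TRIAP1, DDB2 and CCNG1, at least 2-fold higher. The median nearest 0 over 4 other scalings was 0.27, above the random lists each time. For the scalings that differ only by a constant for each array this rank is no test, as for the replication genes. Loess scaling also left the list above the random lists, a rank that is again no test because these lists are matched on level. The list median itself stayed at 0.27 or more under loess scaling. This argues against a scaling difference that changes with level as the whole cause. For the list as a whole the insert alone, with the same effect at both times, is argued against by a median of 0.19 at 24 h against 6 h, which stood apart under the 4 other scalings and with both probe set alternatives (0.087 and 0.062). With the floor at the 70th percentile, left out of that test, it was 0 and did not. The time of harvest stays open for this 24 h against 6 h difference as well, since it goes together with the time after irradiation. The 24 h median of 0.34 is taken against a control collected with the 24 h cells, so the time of harvest does not enter that value. An insert effect joined with a harvest difference is therefore not argued against for the p53 targets. For TRIAP1 and DDB2, already at least 2-fold higher at 6 h, a constant insert effect stays open. Their 24 h against 6 h differences of 0.19 and 0.29 are below the probe set SD of 0.31. A low reading on the single control array stays open for both genes too. They were among 11 genes at least 2-fold higher at both times, against a simulated mean of 8.72 (range 2 to 17) with no change. The noise in that simulation was an upper estimate. On the control array TRIAP1 had a level of 1.13, near the floor, and DDB2 one of 3.55, and neither gene had another probe set. For all 4 genes p53 function left in the GSE56 cells and regulation without p53 cannot be told apart. Unirradiated GSE56 cells and irradiated vector cells, which could separate them, were not analysed here.

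On the 6 h array 17 genes, among them ARR3, RTEL1, KIF1C, MSI1 and WNT11, were at least 2-fold lower than on both other arrays. Probe sets whose names carry r, f or i, which mark a less specific design, held 5 of the 17 (29.4%, against 4.23% of all genes), and 12 rested on other probe sets, so this design is not the whole cause. Noise of single probe sets gave at most 2 such genes in 200 simulated sets, but the simulation gave every level the same noise and leaves out larger noise of low probe sets, so noise cannot be told apart from a change. Another probe set was measured for CLDN9 and WAS, with 6 h log2 differences of 0.10 and -0.45 from the control and -0.70 and -0.85 from the 24 h array, each smaller than 2-fold. No biological explanation was tested for this pattern.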

How the results depend on the processing

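Scaling to trimmed means, medians over members above the floor, and counts without probe sets marked r, f or i were chosen after seeing the data. A list median counted as moved when it shifted by more than its random lists spread, and by at least 0.1, a named gene by more than the probe set SD, and a count by more than 1.5 times. Of 2489 alternative values of 272 results, 2192 stayed within these limits, 293 moved and 4 changed direction. A change of direction was counted only for list medians that stood apart and for genes at least 2-fold different. Other changes of sign are among the values that moved or stayed within the limits. Of 17 list medians that stood apart, 10 did so under all 9 settings of scaling, floor and probe set: mitosis genes and G1/S genes in 3 comparisons each, p53 targets and the respiratory chain at 24 h against the control, and the respiratory chain and ribosomal proteins at 24 h against 6 h. Of the medians that did not, 10 stood apart under at least 1 setting. Random lists not matched on level made 30 medians stand apart, among them the 17. Of 1759 values of named genes, 161 moved, and 2 changed direction with suffix-free probe sets, PTGDS to -1.31 and MNAT1 to -0.37 at 6 h. Values below the floor give no measured difference, which limits lists of low genes; except where fewer or more members or genes enter by construction, the cause was not tested.

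The counts depended most on the floor and the fold threshold. With no floor, 587 genes were higher and 590 lower at 6 h, 616 and 639 at 24 h, and 616 and 624 at 24 h against 6 h. With the floor at the 30th percentile these were 167 and 221, 208 and 250, and 238 and 205, and at the 70th percentile 4 and 22, 26 and 44, and 32 and 37. A threshold of 1.5 gave 228 and 289, 377 and 443, and 354 and 361, and a threshold of 3 gave 3 and 13, 10 and 21, and 12 and 10. Genes higher at both times numbered 65, 2 and 298 with the floor at the 30th percentile, the 70th percentile and none, and 7 with the median over probe sets. Genes lower at both times numbered 77, 11 and 223 with those floors.

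With arrays as deposited the genes above the floor on both arrays had a median difference of -0.12 at 6 h, against 0.013 with quantile normalization, and list medians moved with it. At 6 h they were -0.81 for mitosis genes, 0.20 for G1/S genes, -0.15 for androgen-responsive genes, -0.25 for unfolded protein stress and 0 for sterol synthesis. They were -0.14 for glycolysis, -0.32 for ribosomal proteins, -0.092 for proteasome subunits and -0.10 for the respiratory chain, a counted change of direction. The glycolysis and proteasome medians changed sign too, from 0.026 and 0.088 with the main settings. At 24 h DNA repair had -0.25 and the respiratory chain -0.24, and at 24 h against 6 h ribosomal proteins had 0.29. Arrays scaled to their medians gave at 6 h -0.81 for mitosis genes, 0.20 for G1/S genes, -0.15 for androgen-responsive genes, -0.25 for unfolded protein stress and 0 for sterol synthesis. They gave -0.14 for glycolysis, -0.32 for ribosomal proteins, -0.093 for proteasome subunits and -0.10 for the respiratory chain, again a counted change of direction. The glycolysis and proteasome medians again changed sign. At 24 h they gave -0.25 for DNA repair and -0.24 for the respiratory chain, and at 24 h against 6 h 0.29 for ribosomal proteins. Trimmed-mean scaling gave ribosomal proteins -0.17 at 6 h and 0.25 at 24 h against 6 h.

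With the floor at the 30th percentile, interferon-stimulated genes had 0.16 and sterol synthesis 0.26 at 6 h. At 24 h against 6 h the medians were -0.52 for mitosis genes, 0.33 for histone genes, -0.26 for DNA repair, -0.14 for immediate early genes and 0.11 for androgen-responsive genes. With the floor at the 70th percentile, mitosis genes had -0.44 and sterol synthesis 0 at 6 h. At 24 h p53 targets had 0.0099, mitosis genes -0.87, G1/S genes -0.32 and DNA repair 0. At 24 h against 6 h p53 targets had 0, mitosis genes -0.18, G1/S genes -0.67 and DNA repair 0.

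With no floor the 6 h medians were 0.16 for p53 targets, -0.27 for histone genes, 0.12 for NF-kB targets, 0.25 for interferon-stimulated genes and 0.26 for sterol synthesis. Neuroendocrine markers had -0.26, fibroblast markers -0.29 and leukocyte markers -0.18. At 24 h they were 0.15 for histone genes, 0.28 for NF-kB targets, 0.24 for interferon-stimulated genes, 0.15 for sterol synthesis, -0.16 for neuroendocrine markers, 0.15 for fibroblast markers and 0.10 for basal markers. At 24 h against 6 h they were 0.29 for p53 targets, -0.52 for mitosis genes, 0.40 for histone genes, -0.26 for DNA repair and -0.17 for immediate early genes. Androgen-responsive genes had 0.11, fibroblast markers 0.37, leukocyte markers 0.29 and basal markers 0.35.

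Over members above the floor the 6 h medians were 0.16 for p53 targets, -0.15 for histone genes, 0.12 for NF-kB targets, 0.25 for interferon-stimulated genes and 0.13 for apoptosis regulators. Sterol synthesis had 0.24, fibroblast markers -0.14 and basal markers 0.23. At 24 h they were 0.20 for histone genes, 0.22 for NF-kB targets, 0.36 for interferon-stimulated genes, 0.11 for fibroblast markers, 0.10 for leukocyte markers and 0.15 for basal markers. At 24 h against 6 h they were 0.29 for p53 targets, 0.40 for histone genes, 0.11 for NF-kB targets, -0.14 for immediate early genes and 0.13 for interferon-stimulated genes. Androgen-responsive genes had 0.17, sterol synthesis -0.15, neuroendocrine markers 0.17, fibroblast markers 0.20 and leukocyte markers 0.25. For p53 targets the median over probe sets gave 0.16 at 6 h, 0.19 at 24 h and 0.087 at 24 h against 6 h, and suffix-free probe sets gave 0.22 at 24 h and 0.062 at 24 h against 6 h. No paired analysis was possible because each group has 1 array.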

Other observations

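The genes in this part were chosen after their values were seen. On the 24 h array 26 genes were at least 2-fold higher than on both other arrays. Among them ASS1, argininosuccinate synthase of arginine synthesis, had levels of 10.3 on the control array, 11.2 at 6 h and 25.8 at 24 h. SLC39A7, a zinc transporter of the endoplasmic reticulum, was 2.21-fold above the control and 2.99-fold above the 6 h level, and APP, the amyloid precursor protein gene, had levels of 4.10, 4.23 and 8.63. S100P had levels of 27.5, 20.1 and 65.7. On the same array 33 genes were at least 2-fold lower than on both others. EZH2, a histone methyltransferase gene, had levels of 8.81, 9.48 and 4.40, and ZWINT, a kinetochore gene, 24.5, 30.4 and 10.9. MELK, a mitotic kinase gene, had levels of 3.96, 2.92 and 1.30, and MCM2, a subunit of the replicative helicase, was 2.27-fold below the control and 2.79-fold below the 6 h level. Each of these values comes from 1 probe set on 1 array.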
